A study of Komagataella pastoris with 3 samples.

How the data were processed

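Messenger RNA of Pichia pastoris GS115 was measured by RNA sequencing in cells grown in YPD, a rich medium of yeast extract, peptone and glucose, and collected after 24, 36 and 48 h. Per the labels' protocols, cells were lysed by bead beating, total RNA was extracted, mRNA was taken from it with beads, and libraries were made with a VAHTS Universal V6 kit for Illumina sequencing. The submitters' processing notes name CASAVA and HISAT2 2.1.0. The program that turned alignments into gene values, the genome build, the annotation, the strandedness of counting and any filters are not given in the sources used here.

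The deposited table gives 1 FPKM value per gene and library for 5040 genes, per the file headers, and no replicates were pooled into a column. FPKM divides a gene's fragments by its length and by the mapped fragments of the library, so that a fall of a few abundant genes raises the values of all others. The columns were matched to time points by the codes in the sample titles. There were 3 libraries and 1 per time point, so leaving out a replicate, an error between replicates and a test across samples were not possible, and all p-values were left out except that of 1 gene-order test in the closing section. Depth was looked for in the low values. For genes under 3 FPKM in both libraries of a comparison, 19 to 34 genes, the best common scaling placed 17.6% to 31.6% of ratios within 0.2% of a ratio of small whole numbers. In 20 jittered copies of the values the best reached 23.5% to 32.0%, so whole reads could not be recovered and the depth is unknown. A value of 0 was listed in at least 1 library for 11 genes, of which 4 were at 0 in every library. As 3 of the 11 reached 10 FPKM or more in another library, a 0 is given here only as listed at 0.

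The identifiers are locus tags of the form PAS_chr3_0932, and the table does not pair them with gene names. The reference table at hand covers 5305 genes of Komagataella pastoris ATCC 28485, another species, and 0 of the 5040 tags matched it. The 30 gene lists fixed before the data were examined, on ribosomal proteins, central carbon metabolism, methanol utilization, protein folding, autophagy, transport, the cell cycle, mating and other functions, therefore had no members, and their medians have no value. The rule for named genes, the 10 largest rises and falls per comparison among genes with a given function, named 0 genes for the same reason. In its place 2 tags per direction are given.

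Values were compared as differences of log2(FPKM + 1), which understates the change of low genes. Genes with at least 1 FPKM in at least 1 library were kept, which left 5028 and removed 12. A gene counted as higher or lower when its difference was at least 1 in size, a 2-fold rule of size fixed in advance and not a test. Comparisons were 36 h against 24 h, 48 h against 36 h, and 48 h against 24 h. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 10, no filter and a filter at 10 FPKM, scaling by the median of ratios or by an unweighted trimmed mean of log ratios (trimming 30% of ratios and 5% of levels on each side), and a 4-fold rule. Expression classes were 10 equal classes of the genes by mean log2(FPKM + 1). Random lists, 10000 per group, were matched on 20 level bins, for medians and for counts of higher and lower genes. Bootstrap intervals, with 2000 resamples of genes or pairs at 95%, describe the spread over genes and not between samples. The division of genes by abundance, by identifier prefix and by neighbouring tags was added after the data were examined.

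The counting step was tested on simulated data for 36 h against 24 h. Among 5028 genes with a noise SD of 0.2 on the log2 scale, 81.0% of 100 genes changed 2.5-fold and 99.0% of 100 genes changed 4-fold were called, and 1 of 4828 unchanged genes was called. The noise was assumed and not measured. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.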

Results

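The data were messenger RNA levels of Pichia pastoris GS115, a methylotrophic yeast strain widely used to produce recombinant proteins and now usually classified as Komagataella phaffii. A single shake-flask regime in rich glucose medium was sampled after 24, 36 and 48 h, with 1 library per time point. The table held 5040 genes, each with an FPKM value (fragments per kilobase of gene scaled to the mapped fragments of the library) in each library. FPKM totals were 871921 at 24 h, 785727 at 36 h and 760684 at 48 h, and median gene levels were 54.3, 48.2 and 51.4 FPKM. The sequencing depth is unknown, because the values are already normalized. As no time point was replicated, no value has a replicate error, no p-value across samples is given, and each comparison is one between libraries. Genes are given as locus tags without names or functions, so groups of genes are described by their level and their profile.

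At each time point a small part of the genome held much of the messenger RNA signal, and the genes that made up this part differed between time points. The 100 genes with the highest values held 39.6% of total FPKM at 24 h, 38.3% at 36 h and 37.2% at 48 h. Of these 100 genes, 34 were shared between 24 and 36 h, 51 between 36 and 48 h, 14 between 24 and 48 h, and 13 among all 3 libraries. A level of at least 1000 FPKM was reached by 138 genes at 24 h, 98 at 36 h and 102 at 48 h. Of the 237 genes that reached it in any library, 88 did so at 24 h only, 19 at 36 h only and 50 at 48 h only, while 21 did so in every library. The 50 genes above this level at 48 h only had a median of 126 FPKM at 24 h, 488 at 36 h and 1533 at 48 h, and their share of total FPKM was 1.06%, 3.23% and 13.6%. The 88 genes above it at 24 h only went the other way, with medians of 2492, 468 and 268 FPKM and shares of 25.7%, 5.63% and 3.57%. These sets were chosen by the same values, so their direction follows in part from how they were chosen.

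The first comparison asked how the transcriptome at 36 h differed from that at 24 h. The genes that were abundant at 24 h, a set chosen by a value that enters the comparison, differed in how far they changed. Of the 138 genes with at least 1000 FPKM at 24 h, 88 were at least 2-fold lower at 36 h, 73 of them at least 4-fold lower, and 10 were at least 2-fold higher. The 73 genes had a median change of -2.53 on the log2 scale and an interquartile range from -2.76 to -2.38, a spread that the 4-fold limit itself narrows. Their median level was 2678 FPKM at 24 h and 458 FPKM at 36 h, and their joint share of total FPKM was 22.8% at 24 h and 4.23% at 36 h. The other 65 abundant genes had a median change of -0.22, with an interquartile range from -0.85 to 0.39, and held 22.8% of total FPKM at 24 h and 25.9% at 36 h. With median-of-ratios scaling of the libraries the median change was -2.29 for the 73 genes and 0.02 for the other 65. With trimmed-mean scaling it was -2.32 for the 73 genes and -0.008 for the other 65, whose median thus lay near no change under both scalings.

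Among all 5028 genes with at least 1 FPKM in at least 1 library, 476 were at least 2-fold higher at 36 h than at 24 h and 973 at least 2-fold lower on the log2(FPKM + 1) scale. The remaining 3579 genes, 71.2%, were within 2-fold. At least 4-fold differences were seen in 131 genes that were higher and 261 that were lower. At 8-fold or more there were 57 higher and 41 lower genes, so the excess of lower genes did not hold at that size. Steps from a low to a high level were found as well: 12 genes went from under 100 FPKM to at least 1000 FPKM and 0 genes made the opposite step. The median gene changed by -0.21. Rescaling each library by the median of its ratios to the geometric mean removes most of such a shift by construction, and this median became 0.02. It gave 647 higher and 729 lower genes, which raised the share of higher genes among those changed from 32.9% to 47.0%. The Pearson correlation of log2 levels across genes was 0.79 and Spearman's rho was 0.78, where genes are not independent replicates.

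**Figure D1:**
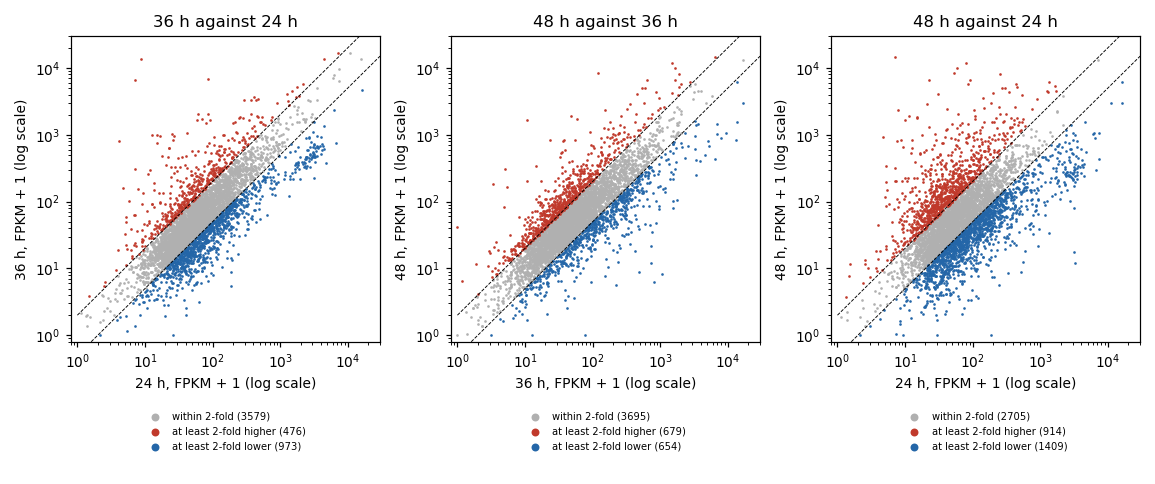
Each point is 1 of 5028 genes, with FPKM + 1 in the earlier library on the x axis and in the later library on the y axis, both on log scales, and dashed lines mark 2-fold differences. In the left panel, the 73 abundant genes at least 4-fold lower at 36 h have medians of 2678 FPKM at 24 h and 458 FPKM at 36 h, and the points are most scattered in the right panel, 48 h against 24 h.

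The second comparison, 48 h against 36 h, showed about as many higher as lower genes with the deposited scaling. There were 679 genes at least 2-fold higher at 48 h and 654 at least 2-fold lower, while 3695 genes, 73.5%, were within 2-fold. Median-of-ratios scaling gave 678 higher and 656 lower genes, and trimmed-mean scaling 719 and 615. At 8-fold or more, with the deposited scaling, there were 32 higher and 55 lower genes. Of the 98 genes with at least 1000 FPKM at 36 h, 50 were at least 2-fold lower at 48 h, 30 of them at least 4-fold lower, and 11 were at least 2-fold higher. The same 98 genes had 50 at least 2-fold higher and 5 at least 2-fold lower at 36 h than at 24 h, and of the 102 genes with at least 1000 FPKM at 48 h, 51 were at least 2-fold higher and 10 at least 2-fold lower than at 36 h. Genes chosen by a high value in a library tend by that choice to be lower in the other, so these counts show no trend of abundant genes. The 65 genes that were abundant at 24 h without the 4-fold drop by 36 h had a median change of -1.05 in this interval, and 34 of them were at least 2-fold lower. The 73 genes with the early drop had a median change of -0.86, with an interquartile range from -1.10 to -0.59, and 26 of them were at least 2-fold lower. The median gene changed by 0.03, Pearson's correlation across genes was 0.82 and Spearman's rho was 0.82.

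Over the whole course, 48 h against 24 h, 914 genes were at least 2-fold higher and 1409 at least 2-fold lower, and 2705 genes, 53.8%, were within 2-fold. Differences of at least 8-fold were found in 149 genes that were higher and 177 that were lower. Of the 138 genes abundant at 24 h, 5 were at least 2-fold higher at 48 h, 10 were within 2-fold, and the others were at least 2-fold lower, 97 of them at least 4-fold. Of the 102 genes abundant at 48 h, 83 were at least 2-fold higher than at 24 h and 11 at least 2-fold lower. From under 100 FPKM to at least 1000 FPKM went 28 genes, and 7 went from at least 1000 FPKM to under 100 FPKM. The median gene changed by -0.25. With median-of-ratios scaling, under which that median was -0.03, there were 1115 higher and 1137 lower genes, and the share of higher genes among those changed was 49.5% in place of 39.3%. Pearson's correlation across genes was 0.58 and Spearman's rho was 0.58.

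The locus tag with the largest rise from 24 to 48 h, PAS_chr3_0932, had 6.05 FPKM at 24 h, 6497 FPKM at 36 h and 14606 FPKM at 48 h, where it was the most abundant gene of the table. Its log2(FPKM + 1) change over the whole course was 11.02. PAS_chr3_0836, with the next largest rise, had 6.83 FPKM at 24 h, 153 FPKM at 36 h and 2356 FPKM at 48 h, a change of 8.23. The largest drop was in PAS_chr2-1_0016, which had 3206 FPKM at 24 h, 732 FPKM at 36 h and 10.99 FPKM at 48 h, a change of -8.06. PAS_chr1-1_0382 had 3160 FPKM at 24 h, 225 FPKM at 36 h and 16.8 FPKM at 48 h, a change of -7.47. By their tags, the 2 genes that were higher lie on chromosome 3, and the 2 that were lower on chromosomes 2 and 1. Positions, exons and functions were not used here, as no annotation of this strain was at hand. The 4 tags were chosen after the values were seen, as the 2 largest changes in each direction among genes with at least 10 FPKM in 1 of the 2 libraries and no value listed at 0.

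Placing each gene by its change in both intervals gave 9 profiles. The largest, within 2-fold in both intervals, held 2740 genes, 54.5% of those examined, and 28.7% of total FPKM at 24 h, 30.4% at 36 h and 31.6% at 48 h. The 130 genes at least 2-fold higher in both intervals held 1.01%, 5.94% and 23.9% of total FPKM at the successive times, with medians of 28.0, 121 and 459 FPKM. The 151 genes at least 2-fold lower in both intervals held 13.2%, 3.37% and 1.18%, with medians of 156, 54.5 and 14.05 FPKM. The 690 genes that were lower at 36 h and then within 2-fold held 27.6%, 7.51% and 6.58%. The 422 genes within 2-fold until 36 h and lower at 48 h held 19.6%, 22.9% and 6.16%, and the 417 genes within 2-fold until 36 h and higher at 48 h held 2.29%, 2.84% and 10.4%. A peak at 36 h was seen in 81 genes, which held 2.15%, 11.5% and 2.28%, and a low point at 36 h in 132 genes, which held 1.02%, 0.32% and 1.07%.

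**Figure D2:**
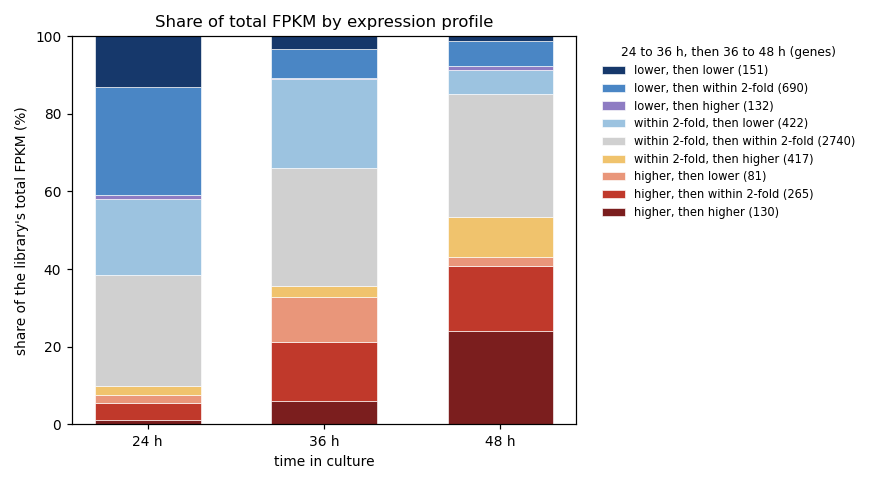
Stacked bars give the share of each library's total FPKM, in percent, held by genes of each of the 9 profiles at 24, 36 and 48 h, with the number of genes in parentheses. Genes higher in both intervals grow from 1.01% to 23.9% of the total, and genes lower at 36 h and then within 2-fold shrink from 27.6% to 6.58%.

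Had the calls of both intervals been independent, 64.3 genes would have been higher in both, 127 lower in both, 61.9 higher then lower, and 131 lower then higher, against 130, 151, 81 and 132 observed. Both intervals share the 36 h library, so its chance deviations enter them with opposite sign. The correlation across genes between the change from 24 to 36 h and that from 36 to 48 h was 0.05, with a 95% bootstrap interval over genes from 0.01 to 0.09 and a Spearman's rho of 0.10. In simulated libraries with no change and equal independent noise it was -0.50. The simulation leaves out real changes, and the noise of these libraries could not be estimated without replicates.

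Steady expression was the exception among abundant genes. Of the 100 genes with the highest mean log2 level over the 3 libraries, 9 had a range under 1 on the log2 scale, 3 of them under 0.5, and the median range was 2.52. Among all 5028 genes, 2209 had a range under 1, 846 of them under 0.5, and the median range was 1.12. The 5 steadiest of the 100 abundant genes had ranges of up to 0.62, with values between 769 and 2276 FPKM.

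Low and high expression classes differed in their median change. With genes divided into 10 classes by mean log2 level, the lowest class changed by -0.72 from 24 to 36 h, with 197 genes at least 2-fold lower and 13 at least 2-fold higher. The highest class changed by 0.14, with 110 genes lower and 129 higher. Classed by the 24 h level, which enters this interval, the direction turned, with 0.17 for the lowest and -0.54 for the highest class. Classed by the 48 h level, which does not enter it, the lowest class changed by -0.92 and the highest by 0.68. From 36 to 48 h the lowest class changed by -0.03, or by 0.0002 with trimmed-mean scaling, and the highest by -0.31. These values depend on how genes are classed: by the 24 h level, which does not enter this interval, the lowest class changed by 0.51, with 158 genes at least 2-fold higher and 28 lower, and the highest by -0.70. Over the whole course the lowest class changed by -0.84, the sixth class by 0.02 and the highest by -0.39, against -0.25 for all genes. With median-of-ratios scaling these 3 values were -0.63, 0.25 and -0.16. From 24 to 36 h they were -0.50 for the lowest and 0.38 for the highest class.

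**Figure D3:**
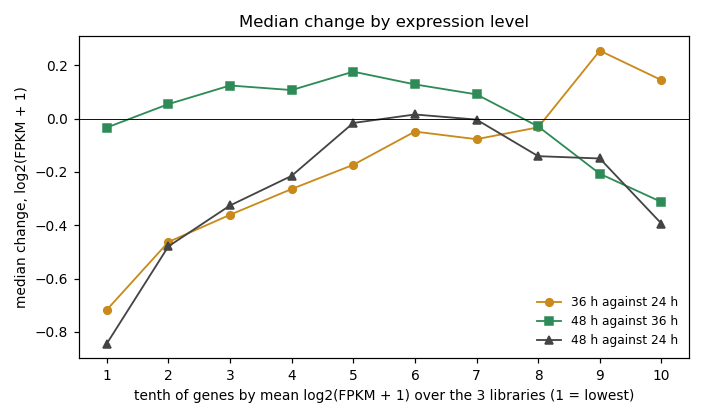
Points give the median log2(FPKM + 1) change, on the y axis, of each of 10 equal classes of the 5028 genes ordered by mean level on the x axis, for the 3 comparisons. The lowest class reaches -0.84 over the whole course, and the highest class is at 0.14 in the first interval and -0.31 in the second.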

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

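Of 48 counts of higher and lower genes under the alternatives, 42 were within 1.5 times the reported count, and 34 of 36 profile counts were. The counts with no filter could not differ, since genes under 1 FPKM in every library cannot reach the 2-fold rule. A count within this band does not mean that the balance of higher and lower genes was kept. With the 4-fold rule, which is stricter by construction, there were 131 higher and 261 lower genes for 36 h against 24 h, 142 and 149 for 48 h against 36 h, and 341 and 498 for 48 h against 24 h. With a pseudocount of 10, which shrinks differences of low genes, 81 genes were lower in both intervals and 41 lower then higher. None of the 4 tags named changed direction under the pseudocounts and scalings, which tests little, as they were chosen for the largest changes. The median change of all genes from 24 to 36 h went from -0.21 to 0.02 with median-of-ratios scaling, which removes most of such a shift by construction. Trimmed-mean scaling gave 615 higher and 753 lower genes for 36 h against 24 h and 1137 and 1108 for 48 h against 24 h. The excess of lower genes over the whole course thus rests on the deposited scaling. Total FPKM fell as well, from 871921 at 24 h to 785727 at 36 h and 760684 at 48 h. The median gene changed by -0.21 and -0.25 against 24 h, so part of the excess may reflect the lower totals. From 36 to 48 h the total also fell, while the median gene changed by 0.03. Neither the cause of the lower totals nor their part in the excess was tested. Leaving out genes listed at 0, chosen after seeing the data, gave 476 higher and 968 lower genes for 36 h against 24 h. The change of PAS_chr3_0932 ranged from 9.83 to 11.25 and that of PAS_chr2-1_0016 from -7.26 to -8.18 over the pseudocounts and scalings. Gene list medians could not be computed under any setting, as the lists had no members. No paired analysis was possible because each time point has 1 library. Unknown depth and the lack of replicates limit every value, most of all those of genes with few FPKM.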

Other observations

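Of the tests in this part, those of the chromosomes, the shuffling of gene order and the share of variance held by level were chosen after results had been seen. Median changes differed little between the chromosomes given by the prefix of the tags. In both comparisons with 24 h, the share of genes at least 2-fold higher was highest on chromosome 4. For 48 h against 24 h the median change was -0.28 over 1449 genes of chromosome 1, -0.24 over 1328 of chromosome 2, -0.22 over 1174 of chromosome 3 and -0.27 over 946 of chromosome 4. Among 10000 random lists matched on level these medians lay at percentiles 30.3, 58.1, 72.0 and 29.9. The most extreme of all 15 medians of these groups was that of chromosome 3 for 36 h against 24 h, -0.16 at percentile 95.1. For 36 h against 24 h the share of genes at least 2-fold higher was 8.07% on chromosome 1, 8.43% on chromosome 2 and 9.71% on chromosome 3, and on chromosome 4 it was 3.54 percentage points above the 9.47% of all genes. The count on chromosome 4 was 1.34 times the mean of random lists matched on level, at percentile 99.99, the most extreme of 30 such counts computed with the deposited scaling. These lists draw genes singly. They leave out that neighbouring genes changed together, as described below, so such percentiles may be too extreme. For 48 h against 24 h the share on chromosome 4 was 21.6%, against 18.2% of all genes, at percentile 99.7. That comparison shares the 24 h library with the first. For 48 h against 36 h, without the 24 h library, the share was 14.4%, at percentile 77.9. It was 14.1% on chromosome 3 and 13.5% of all genes there. The counts of lower genes on chromosome 4 lay at percentiles from 49.8 to 59.8.

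The 73 genes with at least 1000 FPKM at 24 h that were at least 4-fold lower at 36 h also changed alike afterwards, in an interval that did not enter their choice except through the shared 36 h library. The interquartile range of their change from 36 to 48 h was 0.51, against a median of 1.55 and a lowest value of 0.96 among 10000 random lists matched on their 36 h level. It lay at percentile 0.01, the smallest these lists can give, which argues against a spread of later changes like that of other genes of their 36 h level. The division by abundance that gave this group was added after the data were examined, so the percentile describes a group chosen in hindsight. A hypothesis, not tested here, is that the 73 genes may form a group under common control. Their functions are not known here, and a property they could share that affects the measurement, such as transcript length, was not tested, since no lengths of their transcripts were at hand.

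Genes with consecutive tags changed together more than genes farther apart. Over 4776 such pairs the correlation of the change from 24 to 48 h was 0.125, with a bootstrap interval from 0.10 to 0.15, against 0.02 at a distance of 2 tags and 0.0016 at 10 tags. Successive pairs share a gene, which the resampling of pairs leaves out, so the bootstrap intervals over pairs may be too narrow. Both members were at least 2-fold higher in 228 pairs and at least 2-fold lower in 453, where 158 and 375 would follow from independence. None of 10000 shuffles of gene order within a prefix gave as large a correlation (two-sided permutation p = 0.0001, the smallest they can give, with a highest value of 0.06), which argues against chance. Classes by the mean level of the 3 libraries held a share of 0.032 of the variance of this change. That is the most that a like mean level of neighbours could add to the correlation by itself, and is below its interval. Classed by the 24 h level, the median change was 0.60 in the lowest of 10 classes and -1.49 in the highest. A like level in the 24 h or the 48 h library was not tested. Reads of an abundant gene assigned to its neighbour were predicted to raise the correlation in pairs of unlike level. The correlation was 0.05 in 731 pairs at least 8-fold apart and 0.16 in 1947 pairs within 2-fold. The difference was -0.12 with an interval from -0.19 to -0.04, against the prediction. The test cannot decide, since such reads would also bring the levels of a pair closer together, and this explanation stays open. Overlapping transcripts, tandem copies sharing reads and common regulation of adjacent genes all stay open and untested, as neither strand nor sequence was used here.

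Genes abundant at 24 h were lower later, but how far this is a trend of abundant genes in general stays open. The highest of 10 classes by the 24 h level had a median change of -1.49 from 24 to 48 h, while the highest class by the 48 h level had 1.26, so choosing genes by a library that enters the comparison sets much of the value. Classed by the 36 h level, which does not enter it, the highest class changed by -0.49, and its difference from all genes was -0.24 with a bootstrap interval from -0.37 to 0.01. The 24 h values do not choose these genes. As the interval allows a larger fall than that of all genes as well as none, a wider fall of abundant genes was not decided. How much of the -1.49 came from chance high values at 24 h therefore stays open. Classed by the 36 h level, the next highest class changed by -0.05 and the lowest by -0.84, against -0.25 for all genes. From 36 to 48 h, which the 24 h library does not enter, the highest class by the 24 h level changed by -0.70. The bootstrap interval was from -0.80 to -0.55, with 193 genes at least 2-fold lower and 15 higher. The median gene changed by 0.03. Chance high values at 24 h cannot enter a change from 36 to 48 h, so they did not make this later fall. How far they made the change from 24 to 48 h is not answered by it. The lowest class by the 24 h level went the other way from 36 to 48 h. It changed by 0.51, with 158 genes at least 2-fold higher and 28 lower.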
